A study of Mus musculus with 6 samples.

How the data were processed

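RNA from mouse brain labelled as taken at embryonic day 17.5 was extracted with TRIzol and made into libraries with a TruSeq stranded mRNA kit, per the labels' protocols. Each of the 6 libraries has 1 file with a gene symbol and a value in FPKM, per the file headers. The columns of the libraries labelled DKO carry the letters CKO in the file headers, a name the labels do not explain. TopHat2 2.1.1, Bowtie2 and Cuffdiff 2.2.1 and the mouse genome build mm10 are named per the submitters' processing notes, with no options. The gene annotation, read filters and any scaling between libraries are not given in the sources used here. The values were taken as the authors deposited them, with 24346 rows in the same order in all 6 files and 0 repeated symbols. Their sums were 402832 to 436299 FPKM. Rows of short RNAs (microRNA, snoRNA and scaRNA symbols, without their host genes) made up 1.76% to 6.36% of the sums, the most in control replicate 3, although an mRNA library captures such RNAs poorly.

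FPKM values carry no read totals, so precision is taken from the spread between the 3 libraries of a group. Where whole fragments are counted, values of a low gene are whole multiples of what 1 fragment is worth. The most frequent ratio between libraries over 752 to 817 low rows (under 0.3 FPKM) gave each library's depth relative to DKO replicate 1. Over 1228 low rows with at least 2 libraries at the smallest value, 82.1% of the larger values lay within 2% of a whole multiple. The labels name 3 brains per group and no litters, batches or dates.

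Groups were taken from the genotype labels. Rows with a mean of at least 1 FPKM over all 6 libraries were tested, 13215 in all, on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend). The contrast was the libraries labelled DKO minus the libraries labelled control, with Benjamini-Hochberg adjustment, a threshold of 0.05 and no fold limit. A fold change on this scale understates the change of low genes. On simulated data made from the 13215 rows with 200 changed genes, the fit recovered 69.5% of genes with a log2 change of 0.5, 97.3% with 1 and 99.5% with 2, and 4.70% of calls were false. The simulated genes were independent, and the adjustment is stricter where fewer genes change. In the data 3 rows passed, while Mir546 (log2 fold change 1.60) and Mfap4 (-1.26) did not. Recovery in the data may therefore be lower. The host transcripts of miR-124a were compared with a 2-sided exact permutation test over the 20 assignments of 3 libraries.

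Gene lists of cell types, pathways and miR-124 targets, 39 in all, the tests, and the rule for named genes were fixed before the data were examined. The rule takes the host transcripts, and the 12 genes of largest change past the threshold in each direction, filled up by smallest p. It adds up to 4 members, or the 2 of smallest p where none passed, of the lists of targets, radial glia, cell cycle, immature neurons, maturation and synapses. Ptbp1, Ptbp2, Ctdsp1, Sox9, Lhx2 and Rest are named in any case, and unnamed gene models only among the first 4. Some genes that the rule takes are not reported here. Genes named from other lists are those past the threshold over their own list. Other genes named for tissue levels were chosen after their values were seen. Lists were tested with camera (preset correlation of 0.01), repeated with an estimated correlation and with fry. On simulated data with independent genes, the synaptic vesicle list shifted by 0.2 was called in 100% of 20 runs. Correlation between genes, estimated at 0.11 for this list in the data, was not simulated, so recovery in the data may be lower. No gene of the mitochondrial genome list has a row, and the blood, hindbrain and pituitary lists had 2, 1 and 2 measured rows and were not tested. A further 9 lists of eye cell classes were added after photoreceptor genes were seen among the highest values.

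Symbols were matched to GENCODE M21 (GRCm38, the assembly of mm10): 23268 rows by name and 639 through a RefSeq synonym, with 265 found in RefSeq alone and 174 unmatched. For the seed-site test the longest annotated 3' UTR of each gene was searched, and genes without one were left out. The difference between genes with and without a site was averaged over 10 bins of UTR length and ranked among all words of the same length and G+C number with at least 100 genes. Genes within 5 Mb of the deleted loci were compared with other genes by Fisher's exact test. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 was used for these steps.

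The alternatives were pseudocounts of 0.1 and 0.5, no filter or a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, replicate number as a block, leaving out each library, eBayes without a trend or robust, arrayWeights, and a fold threshold of 1.2. For the seed test they were an 8-base, a 7-base A1 and a 6-base site and another choice of UTR, and for the loci 2 and 10 Mb. Leaving out short RNA rows and adding the eye lists were alternatives chosen after seeing the data.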

Results

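The series set out to compare mouse brains at embryonic day 17.5 with and without 2 of the genes that make miR-124a, a microRNA abundant in neurons, and its title names neuronal maturation as the subject. The labels give 6 libraries. In 3 the mouse is labelled a double knockout (DKO) of miR-124a-1 and miR-124a-2, and in 3 it is labelled a control that is heterozygous for miR-124a-1, so the contrast is not one against wild type. Each library is a stranded mRNA library, and each file holds 24346 gene symbols with a value in FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments). Between 16782 and 17015 of the symbols had a value above 0 in a library. Total read numbers are not among the values used here. The steps between low values gave relative depths of 1.24 for DKO replicate 2, 1.13 for DKO replicate 3, 0.956 for control replicate 1, 1.05 for control replicate 2 and 1.02 for control replicate 3, each relative to DKO replicate 1.

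The transcripts that carry the deleted microRNAs were not detectably lower in the libraries labelled DKO than in the libraries labelled control. Mir124a-1hg, the host transcript of miR-124a-1 (GRCm38 chromosome 14, 64587331 to 64593961), measured 492 ± 24.5 FPKM (SD, n = 3) in the libraries labelled DKO. In the libraries labelled control it measured 480 ± 54.9 FPKM (SD, n = 3). The log2 fold change was 0.04, with a 95% confidence interval from limma of -0.16 to 0.24, and the 2-sided exact permutation test gave p = 0.8. Mir124-2hg, the host transcript of miR-124a-2, is listed under its older symbol 2610100L16Rik (chromosome 3, 17789921 to 17808970). It measured 88.5 ± 16.2 FPKM (SD, n = 3) in the libraries labelled DKO and 102 ± 18.9 FPKM (SD, n = 3) in the libraries labelled control, with a log2 fold change of -0.20, a 95% confidence interval from limma of -0.59 to 0.18 and an exact permutation p = 0.5. With 3 libraries against 3 the smallest p that this test can give is 0.1. The rows of the microRNA precursors Mir124a-1, Mir124a-2 and Mir124a-3 are listed at 0 in all 6 libraries, which checks nothing, since such short RNAs are poorly captured in an mRNA library. The labels do not say which part of each host gene was deleted, and a transcript can stay while the microRNA within it is gone. The host transcripts therefore do not show the loss that the genotype labels name, and directions below are those of the libraries as labelled.

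Genes of the mature retina were among the highest values of all 6 libraries. The rod photoreceptor genes Sag and Gnat1 reached 2841 to 3594 and 2544 to 2861 FPKM. Nrl and Crx, transcription factors of photoreceptors, measured 593 to 679 and 467 to 546 FPKM. Genes of dividing cells, which an embryonic brain holds, were near the floor: Mki67 lay at 0.0765 to 0.262 FPKM and Top2a at 0.127 to 0.341 FPKM, and the median of the cell cycle list was 0.986 to 1.35 FPKM. Neurod6, a factor of cortical projection neurons, measured 0.493 to 1.08 FPKM, and the median of the list of deep-layer cortical genes 5.25 to 5.68 FPKM. The immature neuron list was higher, at 46.8 to 56.7 FPKM, led by Stmn1, a tubulin-binding protein of many neurons, and Neurod1, a factor that photoreceptors also use. Xist lay at 0.0240 to 0.0686 FPKM and the Y-linked gene Eif2s3y at 43.5 to 52.8 FPKM in all 6 libraries. These levels go against the tissue and age in the labels in both groups alike, so each group is named here only by its label.

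**Figure D1:**
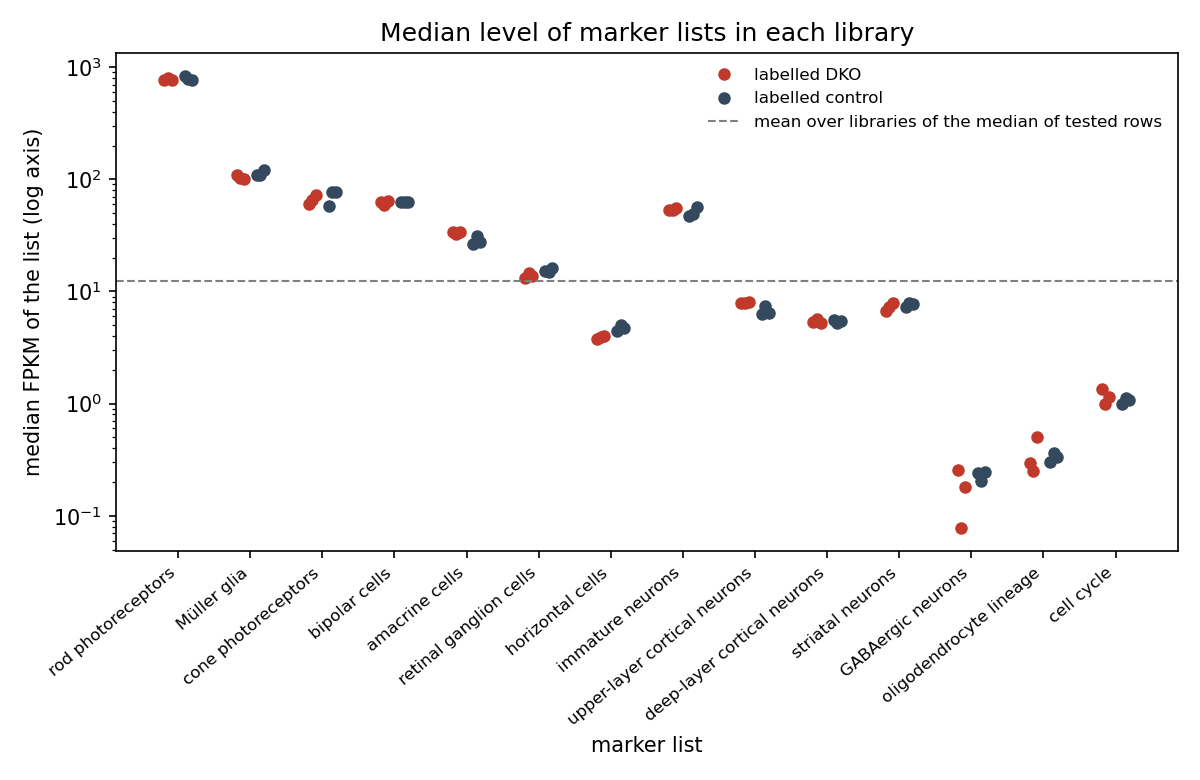
Median FPKM of 14 marker lists (log axis) in each of the 6 libraries, with 1 point per library, red for libraries labelled DKO and dark blue for libraries labelled control. The dashed line is the mean over libraries of the median FPKM of the tested rows. The rod list lies at 765 to 841 FPKM and the cell cycle list at 0.986 to 1.35 FPKM in both groups, and the lists of retinal cell classes were written after rod genes had been seen to be high.

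Dkk3 and Usp47 were higher, and Cyfip2 was lower, in the libraries labelled DKO, and no other of the 13215 tested rows passed the threshold. Dkk3, a secreted glycoprotein of the Dickkopf family (chromosome 7, 112116017 to 112159057), rose from 234 ± 6.15 to 447 ± 29.2 FPKM (SD, n = 3 each), a log2 fold change of 0.93 with SE 0.06 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.00274). Its neighbour Usp47, a deubiquitinating enzyme (chromosome 7, 112023504 to 112111661), rose from 42.6 ± 0.777 to 59.5 ± 1.47 FPKM (SD, n = 3 each), a log2 fold change of 0.47 with SE 0.04 (limma, Benjamini-Hochberg adjusted p = 0.0239). Cyfip2, a subunit of the WAVE complex that controls actin assembly (chromosome 11, 46193850 to 46312859), fell from 53.6 ± 15.7 to 9.91 ± 1.45 FPKM (SD, n = 3 each). Its log2 fold change was -2.29 with SE 0.21 (limma, Benjamini-Hochberg adjusted p = 0.0239). For all 3 genes the values of the groups did not overlap, and fold changes are on the log2(FPKM + 1) scale.

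Among the rows of smallest p that did not pass, the higher ones were of varied kinds. Pla2g4e, a cytosolic phospholipase, had a log2 fold change of 0.99, with 4.73 ± 0.173 against 1.90 ± 0.303 FPKM (SD, n = 3 each; limma, Benjamini-Hochberg adjusted p = 0.0611). The microRNA row Mir546 had 1.60 (adjusted p = 0.0669 in the same limma fit with Benjamini-Hochberg adjustment). In limma with Benjamini-Hochberg adjustment Pla2g4e did pass with robust eBayes (adjusted p = 0.0401), with arrayWeights (0.0290) and without short RNA rows (0.0345), and it missed the threshold in the other alternatives that tested it (0.0547 to 0.340). Mir546 passed with quantile normalization (0.0380) and without DKO replicate 2 (0.00622), against 0.0606 to 0.342 in the others. Other higher rows, each with an adjusted p between 0.142 and 0.196 in limma with Benjamini-Hochberg adjustment, were the glutamate transporter Slc1a2 (log2 fold change 0.32), the neurokinin B precursor Tac2 (0.69), Tfap2b (0.25), Ptprk (0.37), Syce2 (0.56) and AI593442 (0.40). The lower rows that did not pass had adjusted p between 0.118 and 0.196 in limma with Benjamini-Hochberg adjustment. They were Prr7 (-0.58), the secreted neuropeptide precursor Vgf (-0.84), the histone variant H2afx (-0.45), Tpgs1 (-0.43), the cytochrome oxidase subunit Cox5b (-0.28), Adnp (-0.65), Gng4 (-0.44), the microfibril protein Mfap4 (-1.26), Ehd4 (-0.60), the nicotinic receptor subunit Chrna6 (-0.28) and the mitochondrial import protein Timm10 (-0.41). Without control replicate 3, Mfap4 passed (log2 fold change -1.47, limma, Benjamini-Hochberg adjusted p = 0.0498).

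Over all tested rows, 1041 had an unadjusted p under 0.05 in limma, 465 of them higher and 576 lower, where chance would give 661. The groups did not overlap in 1838 rows, or 13.9%, where chance gives 10%. Pearson's r across genes was 0.968 to 0.979 between libraries of the same label and 0.969 to 0.979 between libraries of different labels. Dkk3 passed without each library in turn, and it was the 1 gene called without control replicate 2, with eBayes without a trend and with a fold threshold of 1.2. Usp47 passed in none of those 6 fits (limma, Benjamini-Hochberg adjusted p 0.0556 to 0.182), and Cyfip2 passed only without control replicate 1 (adjusted p 0.000985 there and 0.0562 to 0.182 in the others), while both kept their direction and size.

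**Figure D2:**
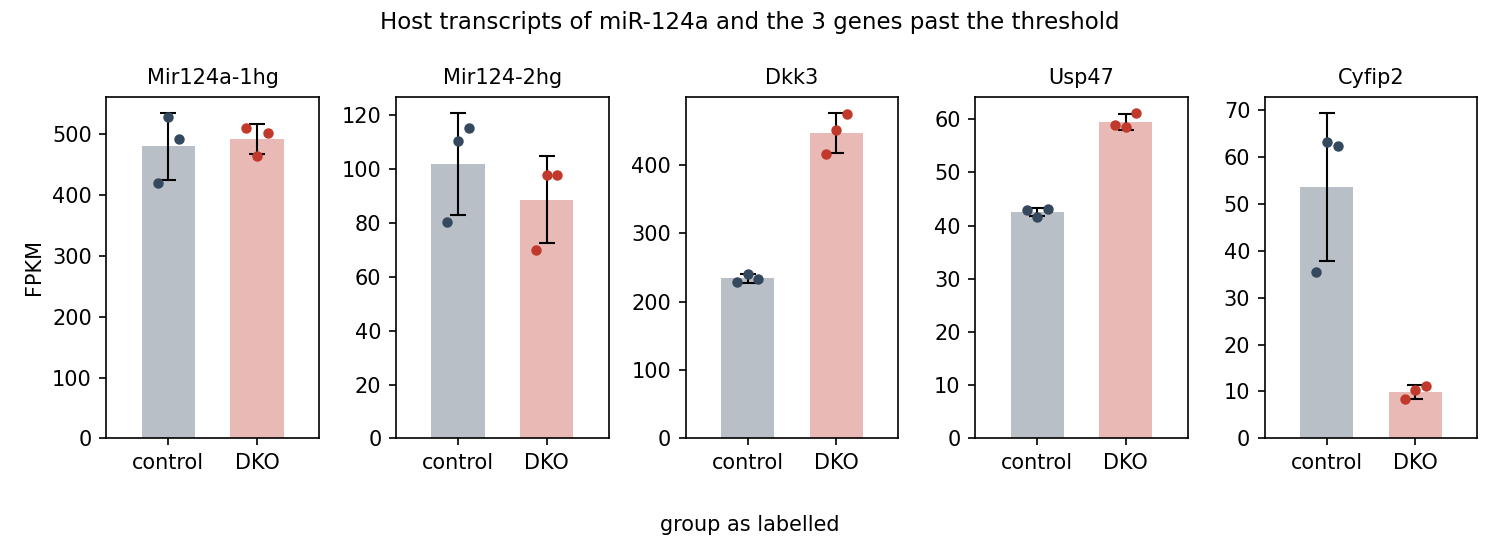
FPKM of both miR-124a host transcripts and of the 3 genes past the threshold, by labelled group. Bars are means of 3 libraries, error bars are SD and points are single libraries, on linear axes from 0. Mir124a-1hg is at 480 FPKM in the libraries labelled control and 492 FPKM in those labelled DKO, while Dkk3 goes from 234 to 447 FPKM.

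Known targets of miR-124, whose transcripts a loss of the microRNA would be looked for in first, were not called as a group. Of 27 measured literature targets, 12 had a log2 fold change above 0 and 15 below, the median was -0.02, and 0 passed when adjusted over the list alone or over all genes. The members of smallest p were Vim (111 ± 6.56 against 129 ± 10.3 FPKM, SD, n = 3 each) and Itgb1 (22.3 ± 1.43 against 24.8 ± 1.05 FPKM, SD, n = 3 each), both lower in the libraries labelled DKO with limma adjusted p of 0.530 and 0.635 (Benjamini-Hochberg). Ptbp1, the splicing repressor that miR-124 is known to hold down, had a log2 fold change of -0.07, and Ptbp2, its neuronal relative, -0.10 (-0.068 without DKO replicate 1). Ctdsp1, a phosphatase that acts with the repressor REST, had -0.08 (-0.055 without DKO replicate 3 and -0.036 without control replicate 2), Rest itself -0.02, and the progenitor factors Sox9 and Lhx2 had 0.12 and 0.0039. None of these 6 genes passed (limma, Benjamini-Hochberg adjusted p 0.692 to 0.994).

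Of 39 gene lists, 35 had at least 3 measured rows. With all 6 libraries, camera with the preset correlation called 0 of the 35, as did camera with an estimated correlation and fry's directional test. Fry's mixed test, which asks whether genes of a list change in either direction, called 14 of them. At an unadjusted camera p under 0.05 there were 6 lists: glutamate receptors, BAF chromatin subunits of neurons, immature neurons and microRNA processing, on the higher side, and neuronal maturation and cerebellum, on the lower side. In the neuronal maturation list, 7 of 23 measured genes were above 0 and 16 below (camera of limma, Benjamini-Hochberg adjusted p = 0.158). The neurofilament genes Nefl, Nefm and Nefh of this list fell when adjusted over the list alone, with Nefm at 66.1 ± 1.06 against 81.6 ± 5.24 FPKM and Nefh at 36.1 ± 0.602 against 42.7 ± 1.94 FPKM (SD, n = 3 each). Nefl and Nefm are also genes of retinal ganglion cells. In the glutamate receptor list, 18 of 25 genes were above 0 (camera of limma, Benjamini-Hochberg adjusted p = 0.158) and 0 passed when adjusted over the list alone. Its member of smallest p was Gria4, with a log2 fold change of 0.15. In the immature neuron list, 11 of 16 genes were above 0, with Stmn1 at 0.15 (0.091 without DKO replicate 1) and Tubb3 at -0.09 (-0.058 with quantile normalization). In the synaptic vesicle list 15 of 22 genes were below 0, with Snap25 at -0.13 and Slc17a6 at -0.14, and 0 passed when adjusted over the list alone. Without control replicate 2, camera with the preset correlation called 2 lists, the glutamate receptors and the BAF subunits of neurons. The estimated correlation was run with all 6 libraries only, where both had an adjusted p of 0.675 (camera of limma, Benjamini-Hochberg).

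Of the progenitor lists, radial glia had 6 of 17 genes above 0, and Tnc, an extracellular matrix protein, rose when adjusted over the list alone (log2 fold change 0.36), while Pax6 had 0.18 and did not pass. The intermediate progenitor list had 5 of 10 genes above 0, and Eomes rose when adjusted over the list alone (0.41). The cell cycle list had 16 of 30 genes measured, 6 above 0 and 10 below, with E2f1 at -0.25 and Ccne2 at 0.25 (-0.42 and 0.43 with a pseudocount of 0.1), and 0 passed. Among lists of neuron classes, Gad1, Gad2 and Slc32a1, the synthetic enzymes and vesicular transporter of GABA, rose and Calb2 fell when adjusted over the GABAergic list alone. In the same way Tac1 and Meis2 rose and Pdyn fell over the striatal list, Slc18a3, Slc5a7 and Isl1 fell over the cholinergic list, and Rprm fell over the deep-layer list. Calb1 and Pcp2 fell over the cerebellar list, Lhx9 rose over the thalamic list and Slc1a2 over the astrocyte list. Of the members named over their own list, 0 passed when adjusted over all genes. Such calls, here and for the other lists, make no allowance for the number of lists searched. Gad1, Gad2, Slc32a1, Pax6, Meis2, Pdyn, Rprm and Slc1a2 lie on chromosome 2, which held more genes of small p than the other chromosomes.

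Transcripts with a miR-124 site in the 3' untranslated region (UTR) were not set apart from transcripts without one by the test used. Of 12535 tested genes with an annotated 3' UTR, 2120 held the 7-base site GTGCCTT, which pairs with positions 2 to 8 of miR-124-3p, and 1059 of these had a log2 fold change above 0. Within bins of UTR length, the mean log2 fold change of genes with a site lay 0.0052 below that of the rest (difference -0.0052). Among 4400 words of the same G+C number, 95% lay between -0.010 and 0.014. These words were not centred on 0, and 7.14% of them lay below the miR-124 site. An exact enumeration over the words gave p = 0.335 as the share with as large an absolute difference, and 0.143 when the lower tail was doubled. Camera on the 2120 genes, whose direction was upward, gave p = 0.808 with the preset correlation, and without the length bins the median was -0.000018 for genes with a site and -0.0022 for the rest, so the sign of the difference depends on how it is measured. In simulated data, with fold changes shuffled over genes, a shift of 0.02 over all site genes was found in 10 of 10 runs. Shuffling removes any link between words and fold changes, and in the data the words were off centre. The reach of the test in the data is therefore not known.

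Genes beside the deleted loci were not called. Within 5 Mb of Mir124a-1 and Mir124a-2 lay 77 tested genes, 57 at the locus on chromosome 14 and 20 at the locus on chromosome 3. Their median log2 fold change was 0.00042, against -0.0017 for all others, and 0 of them passed in limma, against 3 elsewhere (2-sided Fisher's exact test, p = 1). With so few calls in all, 0 among 77 genes was likely in any case, so the count of calls decides nothing. At an unadjusted p under 0.05 there were 10 of the 77 genes, or 13.0%, against 7.84% elsewhere (Fisher's exact test, p = 0.131), and the gene of smallest p was Nefm.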

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

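The block on replicate number left 2 genes past the threshold (Cyfip2 and Dkk3) and 0 lists. Whether the numbers pair the libraries is not settled. The deviations of same-numbered libraries correlated at 0.07, 0.0063 and 0.10, and those of differently numbered libraries at -0.12 to 0.036. Under the block Mir124-2hg had a limma unadjusted p = 0.0021 (Benjamini-Hochberg adjusted p = 0.304), lower in each same-numbered pair. The count of 3 genes stayed within 1.5 times in 15 of 18 alternatives, but the genes behind it changed. Without DKO replicate 1 the called rows were Mir6992, Mir3473g, Dkk3 and Pcsk1n, and without control replicate 3 Mir8113, Mir703, Dkk3 and Mfap4. Snora64 came in without DKO replicate 2 and Snora74a without DKO replicate 3. The count was 1 gene (Dkk3) without a trend in eBayes and 1 with a fold threshold of 1.2. It was 1 to 4 when single libraries were left out, with 1 without control replicate 2. The cause was not tested. Of the named genes, Pla2g4e was gained in 3 alternatives, Mir546 in 2 and Mfap4 in 1. Dkk3 passed in all 18 alternatives, with limma adjusted p (Benjamini-Hochberg) of 0.000436 to 0.0472, and Usp47 and Cyfip2 passed in 9 each. Without control replicate 2 the list count was 2 (neuronal BAF subunits, glutamate receptors), with the preset correlation only, as the estimated one was not run there. With the eye lists added, which brings in other lists, it was 5. The list count of 0 held in the other alternatives. With an estimated correlation each eye list had an adjusted p of 0.149 or more (camera of limma, Benjamini-Hochberg), and fry's directional test called 0. The seed-site difference turned to 0.0012 (exact rank p = 0.848) with the 8-base site, and lay between -0.0068 and -0.0037 without single libraries; p missed the threshold throughout. Mir124a-1hg lay between -0.053 and 0.11 without single libraries, the negative value being without control replicate 1, and Mir124-2hg between -0.36 and -0.04. With arrayWeights Lhx2 turned to -0.0059 and Mir124a-1hg to -0.011. Without single libraries Lhx2 lay between -0.050 and 0.11, Sox9 between -0.017 and 0.29 and Rest between -0.084 and 0.051, none past the threshold. The flanking genes kept their side at 2 and 10 Mb (medians 0.03 and 0.01). Sex as a covariate was not run, because all 6 libraries have Y-linked transcripts and almost no Xist, nor was summing rows of 1 symbol, because 0 symbols repeat. Depth limits low rows most, where 1 fragment sets the step between values.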

Other observations

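Of the tests in this part, the splits for the counts of genes and lists and for the seed site were chosen before their results were seen; the eye lists, the tests of tissue, of the Dkk3 region and of chromosome 2, and the splits by chromosome were chosen after. Of 9 lists of eye cell classes, adjusted together with the other 35, camera with the preset correlation called 5: amacrine cell genes as higher and cone, bipolar, ganglion cell and lens genes as lower in the libraries labelled DKO. With an estimated correlation these calls were lost (camera of limma, Benjamini-Hochberg adjusted p over the 9 lists of 0.149 for amacrine, cone, bipolar and ganglion cells and 0.278 for lens), the other 4 lists were not called either, and fry's directional test called 0 of the 9. Adjusted over the 9 alone, camera with the preset correlation called 7, the rod and horizontal cell lists being the further ones, both lower. The rod list was not called without DKO replicate 1, control replicate 2 or control replicate 3, nor the horizontal cell list without these libraries or DKO replicate 2, and neither was called with quantile normalization (camera of limma, Benjamini-Hochberg adjusted p = 0.262 and 0.0716). With no filter on low values the rod list was not called either (adjusted p = 0.0701 in the same test, camera of limma with Benjamini-Hochberg adjustment). Amacrine cells are inhibitory interneurons of the retina: 9 of 11 measured genes were above 0, and the median log2 fold change was 0.18. Adjusted over the list alone, 7 rose, Gad1, Gad2, Slc32a1, Pax6, Tfap2a, Tfap2b and Tfap2c, and Calb2 fell. Of the 7, Gad1, Gad2, Slc32a1 and Pax6 are among the chromosome 2 genes of small p described further on. Pax6, Gad1, Gad2, Slc32a1 and Calb2 also stand in other lists. In the cone list 10 of 11 genes were below 0, the median was -0.17 (-0.11 without control replicate 2), and the opsin genes Opn1sw and Opn1mw fell when adjusted over the list alone. The bipolar and ganglion cell lists had medians of -0.11 and -0.13, with 11 of 14 and 9 of 12 genes below 0, and the bipolar median was -0.054 without DKO replicate 1. Adjusted over the ganglion cell list alone, Nefl and Nefm fell and Eomes rose (log2 fold change 0.41); Nefl and Nefm also stand in the neuronal maturation list and Eomes in the intermediate progenitor list. Müller glia and the pigment epithelium list, with 3 measured genes, were not called (camera of limma, Benjamini-Hochberg adjusted p = 0.696 and 0.147), except that the pigment epithelium list was called as higher without control replicate 1 (median 0.55, adjusted p = 0.00622). The lens list had a median of -1.10, set largely by control replicate 2, where Cryaa reached 102.8 FPKM against 9.22 to 35.1 FPKM in the other 5 libraries. Without that library the lens median was -0.50.

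Photoreceptor genes are among the highest values of libraries labelled embryonic brain. For a minority of retina tissue in brain samples, the lists of regional brain neurons cannot decide. In any library 0 of 8 had a median above that of the tested rows (12.4 to 12.6 FPKM). The list medians count unmeasured genes (1 of 17 hindbrain genes was measured) and the tested rows do not. For lists with few measured genes a brain library could therefore fall below as well. This explains less for the upper-layer, deep-layer and striatal lists, with 11 of 12, 12 of 14 and 12 of 13 genes measured. Their medians were 6.35 to 8.08, 5.25 to 5.68 and 6.69 to 7.91 FPKM. Where these lists would lie in a brain library was not measured. Cell cycle genes near the floor do go against embryonic brain as most of each library. The deletion that separates the labelled groups is argued against as the source, since the rod list had a median log2 fold change of -0.038 between them (-0.060 to -0.019 without single libraries). This rests on the genotype labels, and the labelled control is itself heterozygous for miR-124a-1. Libraries of mature retina under these labels stay open as a candidate explanation: 5 of 6 other classes of retinal cell had list medians above that of the tested rows in all 6 libraries, and the data do not say how such files would have come to these labels. These bounds replaced a first set after the list values had been seen, and 2 bounds of the first set were not met, one asking for a cell cycle median under 1 FPKM in every library (0.986 to 1.35 FPKM) and one for every retinal class above the tested rows (horizontal cells lay at 3.76 to 5.01 FPKM).

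Dkk3 and Usp47, separated by 4355 bases, are both higher in the libraries labelled DKO. Flanking DNA of another strain over a long segment was tested on the 41 tested genes from 0.5 to 5 Mb away, of which 3 (7.32%) had an unadjusted p under 0.05 against 7.87% of other genes, an odds ratio of 0.924 (95% confidence interval 0.182 to 2.92, Fisher's exact test), so with so few genes it cannot be told apart from no such segment. Extra copies of a segment holding only these 2 genes, such as a transgene built from this locus, are a candidate explanation that stays open, as 0 of the 3 other tested genes within 0.5 Mb (Galnt18, Mical2 and Parva) rose by over 0.26 on the log2 scale at an unadjusted p under 0.05. That bound was set after the values were seen, and Galnt18 lay below it with a log2 fold change of 0.14 (limma, unadjusted p = 0.0444, Benjamini-Hochberg adjusted p = 0.621). An effect of the labelled deletion was not tested for Dkk3 and Usp47 or for Cyfip2. The tissue is at odds with the labels, the host transcripts do not show the labelled loss, and the column names read CKO. The fall of Cyfip2 is therefore not evidence of a response to loss of miR-124a. Whether Cyfip2 was itself altered in these libraries stays open.

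Chromosome 2 held 47 of the 265 genes at an unadjusted limma p under 0.01, or 4.52% of its 1039 tested genes against 1.80% elsewhere (Fisher's exact test adjusted by Benjamini-Hochberg over 20 chromosomes, p = 2.36e-06), a pattern found by looking through 20 chromosomes at 2 thresholds and then through windows of 10 Mb. A changed number of whole copies of chromosome 2 is argued against by a median log2 fold change of -0.0051 over its genes, with 18 of the 47 higher and 29 lower. A linked segment of another strain stays open: 30 of the 47 genes, among them Pla2g4e, Slc1a2, Ehd4 and Timm10, start in the 60 Mb window from position 70553072 on, the last at 130171414, and 0.0041 of 10000 shuffles along the chromosome gave as many, a test whose window was set after the cluster had been seen and which treats neighbouring genes as independent. The labels name no strain, and an effect of the labelled deletion on these genes was not tested. Without single libraries the count was 28 to 36, with 28 without DKO replicate 2 and 31 without DKO replicate 1 or control replicate 3.

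Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 3 genes past the threshold and the highest other split 4, and 3 of the 10 splits gave at least 3. It gave 0 lists, against 3 in the highest other split, so all 10 gave as many. For the size of the seed-site difference the real split gave 0.0052 and the highest other 0.0039, so that 1 split, the real one, was as large. Because chromosome 2 was picked as the extreme of 20 chromosomes in the real split, each split was given its own extreme chromosome. The -log10 of the 1-sided Fisher's exact p was 6.95 in the real split and 3.86 in the highest other, on chromosome 4, and 1 split, the real one, was as large. Rows at an unadjusted p under 0.05 numbered 1041 in the real split and 1311 in the highest other.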
